A study of Mus musculus with 24 samples.

How the data were processed

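Kidney RNA of mice carrying floxed Mop3 (Arntl) alleles, with or without Cre recombinase driven by the albumin promoter, was measured on 24 Agilent arrays. Albumin-driven Cre acts in hepatocytes, so the kidney is a tissue whose own clock gene was not targeted. Per the labels, each array held 1 pool of RNA from at least 3 mice, and the pools cover 6 zeitgeber times (ZT, hours after lights on), 2 genotypes and 2 ages, 10 and 20 weeks. A group was a genotype at a time and held 2 arrays, 1 of each age. No technical or same-age repeats exist, so the spread came from the residuals of a model shared by all arrays.

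Per the file headers, the authors scanned the slides and extracted spots with Agilent Feature Extraction 9.1.3.1, and the deposited scanner files hold the Cy3 and Cy5 mean and background intensity of 45018 spots per array. The deposited value table holds the log10 ratio that the same software wrote. It equalled log10 of processed Cy5 over processed Cy3 on 85.6% of spots, within a tolerance of 1e-05, and was 0 on the other 14.4%. Its direction and scale were thus known, and the median of the deposited ratio was 0 on every array except floxedAlbCre ZT20 at 20 weeks, where it was 0.00628. Per the labels, the sample pools carried Cy3 and a common kidney reference carried Cy5, on every array and with no dye swap.

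Mean intensities were corrected by normexp with an offset of 50 and normalized by loess within each array in limma 3.58.1 under R 4.3.3, with control spots at weight 0. For values of a single channel the same normexp correction was followed by quantile normalization between arrays, without loess. Spots of 1 probe were averaged. Probes well above background in Cy3 on at least 6 of 24 arrays were kept, and the brightest probe stood for its gene, which left 20677 genes. Of 41174 probes, 24375 were named through accessions in the reference table, 6301 through symbols and 2426 through synonyms, and 8072 kept the name of the file. Log2 ratios were fitted in limma on genotype, age, the cosine and sine of a 24 h period and their product with genotype. Age products were added for the tests of age against rhythm and of genotype against age. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. An amplitude is the fitted distance from mean to peak in log2 units, and all errors beside fitted values are standard errors from limma over 24 arrays. The tests of the comparisons, the gene lists and the alternatives were chosen before the data were examined, apart from 3 alternatives: Cy5 alone, a filter on Cy5 signal, and slide as a block for list shifts.

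The ratio's sign was not kept as first planned. The design fixed it as Cy3 over Cy5, after the labels. Signs are printed here as Cy5 over Cy3, a choice made after the values were seen, because clock genes passed as rhythmic in Cy5 alone and none in Cy3 alone. P-values and the numbers of genes called do not depend on this choice, while counts of higher and lower genes change places. Under the labels' dyes every signed difference turns and every peak moves by 12 h.

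The genes named were fixed by rule: Arntl and Alb; 20 clock genes; the 20 genes of largest amplitude past the rhythm threshold with peaks within 4 h in both ages; the 10 largest differences in each direction for age; and, since none passed for genotype, the 5 smallest p-values in each direction. From other lists at most 4 members with the smallest p-values were named. Some genes that this rule names are left out of the text, and counts over genes and lists include them. Lists were 34 in number and covered pathways and cell type markers. Rhythmic members were tested by a one-sided Fisher's exact test, and shifts by camera with an estimated correlation between genes. Alternatives changed the background correction, the source of the ratio, the channel, the filter, the probe per gene, array weights, the form of the time course, the age term, the pair or slide block, the age or genotype included and the threshold, and left out each array in turn. For lists they were camera with a preset correlation of 0.01, fry, and an exact permutation test over 4096 sign flips of the 12 pairs. Per the labels no replicate numbers were given. By design, arrays of the 2 genotypes at the same age and time form 12 pairs. These pairs were a block in 1 alternative, and the fit without an age term was another. In most pairs the 2 arrays lay on different slides.

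Arrays lay on 6 slides of 4, each with its own scan, and no slide held both ages. Slides 1, 4, 5 and 6 held both genotypes. Slides 1 and 5 held 2 arrays of each. Slide 4 held 1 floxed and 3 floxedAlbCre arrays, and slide 6 held 3 and 1. Differences within these slides were taken after the fitted time course of each genotype was removed, and also without that step. The code was tested on simulated data with the residual spread of the real genes and 100 genes changed by 0.5 and 100 by 1 log2 unit per comparison. The simulated noise was independent between genes and arrays, with no slide effect and equal array quality. With many genes changed at once, the adjusted threshold is also easier to pass than where few genes differ. Recovery in the real arrays may therefore be lower. The number of arrays limits the precision, and the median half-width of the 95% interval of a genotype difference was 0.13 log2 units. Median Cy3 signal ranged from 81.4 to 361 and median Cy5 signal from 85.1 to 719. No array was left out of the results given first. The processed signals and saturation flags of the software served for checks only. The flag for signal well above background set the filter. Spots flagged as non-uniform or as population outliers had weight 0 in the loess and were left out of the values. Probes missing on more than 6 arrays were dropped.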

Results

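The data are 24 kidney arrays, 12 from floxed mice and 12 from floxedAlbCre mice, in which albumin-driven Cre removes the clock gene Mop3 (Arntl) from hepatocytes. Each genotype was sampled at 6 times of day, at 10 and at 20 weeks of age, with 1 pool of mice per array. Between 59.6% and 92.7% of probes were well above background in Cy3, and between 60.1% and 98.6% in Cy5. The brightest array was floxedAlbCre ZT20 at 20 weeks, with a median Cy5 signal of 719.

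Clock rhythms lay mainly in Cy5, the dye that the labels give to the reference. Arntl, a core clock activator, had an amplitude of 1.17 log2 units in Cy5 alone and 0.040 in Cy3 alone. Dbp, a transcription factor driven by the clock, had 1.72 in Cy5 and 0.023 in Cy3. Of 20 clock genes, 10 were rhythmic in Cy5 alone and 0 in Cy3 alone, where limma gave 1100 genes an unadjusted p under 0.05. In Cy3 at 20 weeks Nfil3 had a fitted amplitude of 0.61 and Usp2 of 0.37; neither passed in Cy3 over both ages. Cy5 alone was examined only after the ratios were seen. All signs and peak times here are of Cy5 over Cy3, opposite to the labels' dyes, and this direction was chosen after the values were seen. Read with the labels' dyes, every difference changes sign and every peak moves by 12 h.

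**Figure D1:**
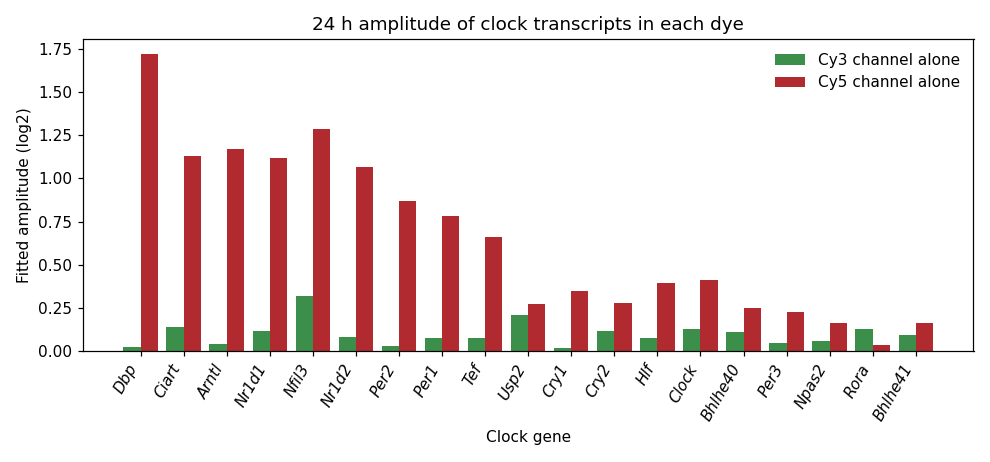
Fitted 24 h amplitude (log2 units) of clock genes, with 1 green bar for Cy3 alone and 1 red bar for Cy5 alone, over 24 arrays each. Dbp reached 1.72 in Cy5 and 0.023 in Cy3.

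Arntl (gene ID 11865, chromosome 7), the floxed gene, was present in kidney in both genotypes. Its mean log2 ratio was -0.12 ± 1.07 (SD, n = 12) in floxed and -0.037 ± 0.78 (SD, n = 12) in floxedAlbCre arrays, a spread that includes the times of day. The difference, 0.088 ± 0.11, did not pass (limma, adjusted p = 0.722). Alb (gene ID 11657, chromosome 5), whose promoter drives Cre, averaged 0.59 ± 0.56 (SD, n = 12) and 0.33 ± 0.61 (SD, n = 12), and its difference of -0.26 ± 0.16 did not pass either (limma, adjusted p = 0.462). Both genotypes lay on slides 1, 4, 5 and 6, with 1 floxed array on slide 4 and 1 floxedAlbCre array on slide 6. These slides did not always hold both genotypes at the same times. Within them, with the fitted time course removed, Arntl differed by -0.056, 0.45, 0.12 and 0.21 and Alb by 0.36, 0.15, -0.74 and -0.052; without that step the differences were -0.16, -0.043, -0.050 and 0.020 for Arntl and 0.58, 0.057, -0.84 and 0.36 for Alb, without a common sign for either. The labels do not state which part of Arntl its probe reads, so its level does not test for a deletion.

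The first comparison asks which kidney transcripts follow time of day. The clock led them: Dbp peaked at ZT8.7 with an amplitude of 1.70 ± 0.077, Ciart, a clock repressor, at ZT8.6 with 1.20 ± 0.14, and Arntl in opposite phase at ZT21.5 with 1.18 ± 0.076. Nr1d1 and Nr1d2, nuclear receptors that repress Arntl, peaked at ZT6.3 (1.16 ± 0.099) and ZT8.7 (1.05 ± 0.086). Nfil3, a repressor that competes with Dbp for its sites, peaked at ZT19.7 (1.08 ± 0.093), and Per2 of the negative limb at ZT12.9 (0.89 ± 0.067). In limma 469 of 20677 genes were rhythmic, with a median amplitude of 0.25, and 34 reached 0.5.

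Other rhythmic transcripts of large amplitude included Slc16a1, a monocarboxylate transporter, with 0.81 ± 0.073 at ZT21.3, Aqp8, a water channel, with 0.78 ± 0.077 at ZT0.0, and Fabp7, a fatty acid binding protein, with 0.63 ± 0.072 at ZT1.9. Tsc22d3 and Sgk1, both glucocorticoid targets, peaked early in the dark phase at ZT13.9 (0.72 ± 0.089) and ZT14.0 (0.58 ± 0.11). Further members of the top 20 were Nat8f5 (0.79 ± 0.089, ZT15.2), Ahsg (0.77 ± 0.18, ZT2.3), Lonrf3 (0.74 ± 0.092, ZT18.6), Nt5e (0.62 ± 0.095, ZT22.3), Rhobtb1 (0.58 ± 0.051, ZT18.7), Per1 (0.68 ± 0.095, ZT10.6) and Tef (0.62 ± 0.054, ZT9.7). Peaks of the 469 genes were most numerous in the windows labelled ZT8, with 108 genes, and ZT12, with 105. Probes of 1 gene differed for Nr1d1, whose other probes had amplitudes of 0.13 and 0.081, for Per2 (0.20 on the other probe) and for Cry2 (0.023), and the smallest on another probe was 0.12 for Tef, 0.22 for Nt5e and 0.087 for Lonrf3. The count was 23 in the 20 week arrays alone, 173 with slide as a block, 2592 with array weights, 307 without floxedAlbCre ZT12 at 10 weeks and 742 without floxedAlbCre ZT16 at 20 weeks. The 10 week arrays alone gave 621 genes. In them ZT0 and ZT4 lay on slide 1 and ZT8 to ZT20 on slides 2 and 3. Time and slide thus partly coincided at 10 weeks. At 20 weeks both ZT0 arrays lay on slide 4 and both ZT12 arrays on slide 5. Of 43 rhythm values of named genes, 30 lost their call in the 20 week arrays alone, 25 in Cy5 alone and 15 with slide as a block. The call of Ahsg, a liver-secreted protein, ended in 17 of the 24 fits that left out 1 array.

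Of the 34 lists, 4 passed the test for a larger share of rhythmic genes than among the other genes; the next, collecting duct principal cells, had 2 of 8 (Fisher's exact test, adjusted p = 0.0893). In the list of Arntl and its partners, which also holds the repressors Cry1 and Nfil3, 5 of 7 were rhythmic, and 6 when adjusted over the list alone. Of the other clock list, of Per genes, other repressors and outputs such as Dbp, 12 of 13 were rhythmic, and 13 when adjusted over the list alone (Fisher's exact test, adjusted p = 2.0e-06 and 7.0e-18). Npas2 (0.16 ± 0.042), Rora (0.13 ± 0.059) and Bhlhe41 (0.12 ± 0.036) did not pass over all genes. The calls of Bhlhe40, Usp2 and Per3 ended in 3, 2 and 1 of the 24 fits that left out 1 array. Renal salt and water transport had 6 of 25, the same number when adjusted over the list alone (Fisher's exact test, adjusted p = 1.4e-04). Its examples are Avpr1a, a vasopressin receptor, with 0.50 ± 0.073 at ZT22.8, Slc9a3, the sodium-hydrogen exchanger of the proximal tubule, with 0.45 ± 0.069 at ZT6.1, Aqp3 with 0.32 ± 0.057 at ZT11.4, and Avpr2 with 0.19 ± 0.034 at ZT21.5. The glucocorticoid-responsive list had 5 of 14, and 12 when adjusted over the list alone (adjusted p = 1.1e-04). Fkbp5, which binds the glucocorticoid receptor complex, peaked at ZT13.8 (0.43 ± 0.071), and Cdkn1a, a cell cycle inhibitor, at ZT22.0 (0.34 ± 0.063). Both lists hold Sgk1, and the glucocorticoid list shares Per1 with the clock.

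**Figure D2:**
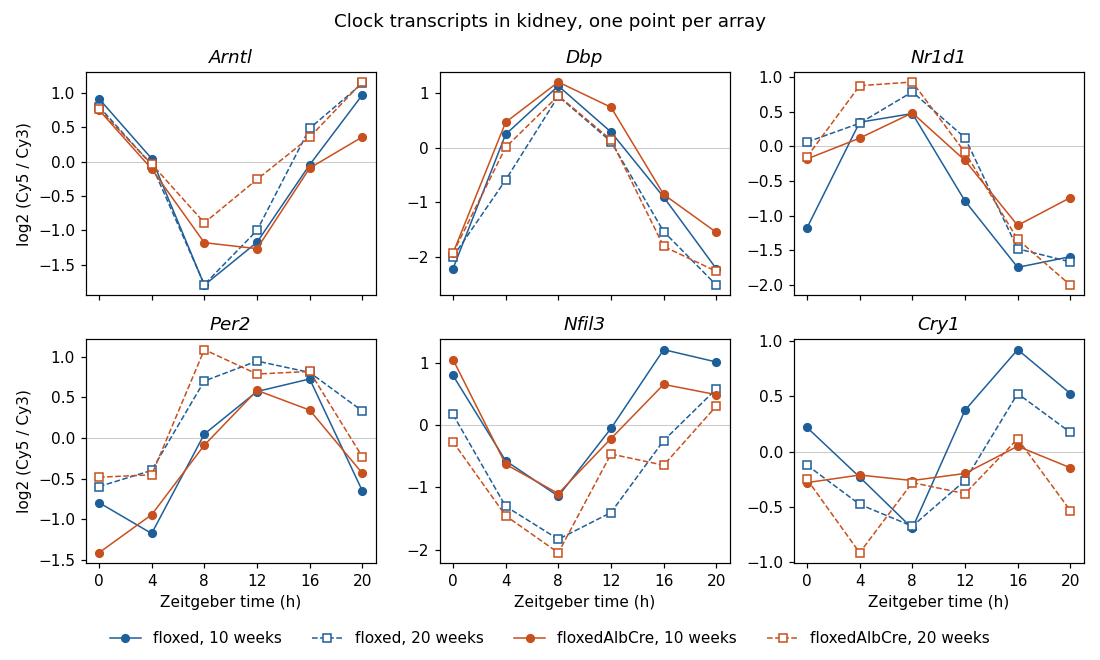
Log2 ratio (Cy5 over Cy3) of 6 clock genes against zeitgeber time in hours, with 1 point per array; blue is floxed, orange floxedAlbCre, filled points 10 weeks, open points 20 weeks. Arntl was lowest at ZT8 in floxed arrays, with a mean of -1.79.

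The second comparison asks whether removing the hepatocyte clock changed rhythms in the kidney. Dbp peaked at ZT8.8 in floxed and ZT8.5 in floxedAlbCre arrays, a difference of -0.27 h with a 95% interval of -0.99 to 0.44 h. For Arntl the peaks were ZT21.4 and ZT21.6, and for Per2 ZT13.3 and ZT12.5. Arntl had amplitudes of 1.40 and 0.96, a difference of -0.44 with an interval of -0.75 to -0.12. Cry1, a repressor of the clock, had 0.61 and 0.20, a difference of -0.41 with an interval of -0.66 to -0.16. On the other probe of Cry1 the amplitudes were 0.34 and 0.25, and the probe used was well above background in Cy5 on 9 and 10 of 12 arrays at 10 and 20 weeks. Neither gene passed over all genes: the limma test of the rhythm difference gave Arntl an unadjusted p of 0.0282 and Cry1 0.00371, with an adjusted p of 0.968 for both. When adjusted over the list alone, 1 gene of the list of Arntl and its partners, Cry1, and 0 of the list of Per genes and outputs passed.

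Across 20677 genes, limma called 0 for a rhythm difference between genotypes, with 1022 at an unadjusted p under 0.05 and a smallest adjusted p of 0.968. Tested within a genotype, 48 genes were rhythmic in floxed and 84 in floxedAlbCre arrays, with 28 in both, and these counts do not show a difference between genotypes. Leaving out 1 array gave 25 to 72 in floxed, the lowest without floxed ZT16 at 10 weeks and the highest without floxedAlbCre ZT20 at 20 weeks, and 22 to 384 in floxedAlbCre, the lowest without floxedAlbCre ZT12 at 10 weeks and the highest without floxedAlbCre ZT16 at 20 weeks. On simulated data without slide effects the same test recovered 65 of 100 genes whose rhythm differed by 0.5 log2 units and 100 of 100 at 1 unit. Where few genes truly differ the adjusted threshold is harder to pass, so recovery may be lower. At 10 weeks from ZT8 to ZT20 each genotype lay on a slide of its own. At 20 weeks the genotypes were unevenly spread over slides 4 and 6.

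The third comparison asks whether mean transcript levels in kidney differ with the hepatocyte clock. No gene passed: limma called 0 of 20677, with 3110 at an unadjusted p under 0.05 and a smallest adjusted p of 0.159. The values with the smallest p, none of which passed, were higher in floxedAlbCre for Il34, a macrophage cytokine, and for Prxl2b, Map1a, Foxp4 and Rasl12, at Il34 (0.36 ± 0.065), Prxl2b (1.05 ± 0.19), Map1a (0.45 ± 0.087), Foxp4 (0.26 ± 0.055) and Rasl12 (0.36 ± 0.079). They were lower for Chrdl1, an antagonist of bone morphogenetic proteins, for Gfpt1, which opens the hexosamine pathway, and for Hs6st2, Nudt11 and Slc4a8, at Chrdl1 (-0.50 ± 0.097), Gfpt1 (-0.23 ± 0.045), Hs6st2 (-0.26 ± 0.053), Nudt11 (-0.29 ± 0.060) and Slc4a8 (-0.23 ± 0.048). Other probes gave smaller differences, of -0.099 for Chrdl1, -0.012 and 0.069 for Gfpt1, -0.055 for Hs6st2, -0.076 and 0.10 for Slc4a8, 0.0084 and 0.13 for Map1a and 0.085 for Foxp4, while the other probe of Nudt11 gave -0.26. Map1a and Foxp4 were well above background in Cy5 on 5 and 6 of the 12 arrays at 10 weeks. Slide 4 held 1 floxed and 3 floxedAlbCre arrays, and slide 6 held 3 and 1. Values from slides 4 and 6 thus rest on a lone array of 1 genotype. Within slides 1, 4, 5 and 6, with the fitted time course removed, Prxl2b differed by 1.12, 1.75, 1.01 and 0.24 and Il34 by 0.32, 0.37, 0.46 and 0.25, while Nudt11 changed sign, at -0.37, 0.031, -0.26 and -0.30. Without that step the sign also turned on slide 6 for Map1a (-0.092), Foxp4 (-0.032), Gfpt1 (0.028) and Hs6st2 (0.044). In the 20 week arrays alone limma called 0 genes for genotype, with 448 at an unadjusted p under 0.05. At 10 weeks the arrays from ZT8 to ZT20 lay on slides of 1 genotype each, so genotype and slide partly coincided there. At 20 weeks the genotypes were unevenly spread over slides 4 and 6, so the 20 week arrays are not free of slide either. The count was 647 without floxedAlbCre ZT16 at 20 weeks, 3 without floxed ZT20 at 20 weeks, 7 with the pairs of same age and time as a block, 1247 with array weights, 1081 in the 10 week arrays alone, and 0 in limma with slide as a block, with 836 at an unadjusted p under 0.05.

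Fatty acid oxidation and PPAR alpha targets had a median genotype difference of 0.16, with 8 of 21 members at an unadjusted p under 0.05 and 4 past the threshold when adjusted over the list alone. Members were Cyp4a14, a fatty acid hydroxylase, at 0.67 ± 0.21, Ucp2 at 0.33 ± 0.11 and Cpt2 at 0.22 ± 0.075, none of which passed over all genes, and within slides 1, 4, 5 and 6 Cyp4a14 differed by 1.02, 1.36, 0.55 and 0.69. The list had adjusted p = 0.461 with an estimated correlation, and 0.0013 with a preset correlation of 0.01. Its median within slides 1, 4, 5 and 6, treated likewise, was 0.17, 0.12, 0.23 and 0.14, and with slide as a block, a setting added after the data were seen, its adjusted p was 0.259. The preset correlation also called ribosomal proteins (adjusted p = 0.00429, median 0.066), skeletal muscle (adjusted p = 0.00429, median 0.090), thick ascending limb (adjusted p = 0.0184, median -0.11) and interferon-stimulated (adjusted p = 0.0333, median 0.054), and these calls ended with adjusted p = 0.461 with an estimated correlation for the first 3 and 0.693 for the last. Acetaminophen bioactivation and conjugation, which the study's title names, had a median of -0.041. It was higher in floxedAlbCre in 1 of 12 pairs (exact permutation test, two-sided, adjusted p = 0.0332). In most pairs the arrays lay on different slides, so the exact test cannot tell genotype from slide. For this list camera gave adjusted p = 0.909 with an estimated correlation, and 0.932 with slide as a block. Its medians within slides 1, 4, 5 and 6 were -0.0025, -0.059, -0.017 and -0.036, and its members Gsta1 (-0.34 ± 0.13) and Gsta2 (-0.34 ± 0.14), glutathione transferases, did not pass and differed by 0.044, -0.12, -0.87 and -0.44 and -0.0013, -0.11, -1.17 and -0.42 within those slides. Of the proximal tubule markers, 7 of 14 passed when adjusted over the list alone, among them Slc27a2 (0.42 ± 0.12) and Miox (0.33 ± 0.096), with adjusted p = 0.693 with an estimated correlation. Within the same slides these differed by 0.14, 0.38, 0.28 and -0.011 and 0.13, 0.42, -0.046 and -0.012, without a common sign. Adipose markers had a median of 0.28 and were higher in floxedAlbCre in 10 of 12 pairs (exact permutation test, two-sided, p = 0.00391, adjusted p = 0.0664; camera adjusted p = 0.693 with an estimated correlation), and 0 of 10 passed when adjusted over the list alone. Their medians within slides 1, 4, 5 and 6 were 0.35, 0.37, 0.0045 and 0.30 with the time course removed and 0.072, 0.053, 0.056 and 0.60 without that step.

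The fourth comparison sets the 20 week arrays against the 10 week arrays. The largest falls at 20 weeks included Cidea, a lipid droplet protein, at -2.28 ± 0.20, Ucp1, the uncoupling protein of brown fat, at -2.23 ± 0.19, Cfd, which fat cells secrete, at -1.48 ± 0.27, and Cox8b at -1.43 ± 0.22. Slc7a12, an amino acid transporter, was higher by 2.90 ± 0.26 and in 12 of 12 pairs. Also lower were Slc22a7 (-1.48 ± 0.11), Slc22a26 (-1.43 ± 0.10), Car15 (-1.36 ± 0.12), Aoc1, the diamine oxidase (-1.31 ± 0.073), Mfsd2a (-1.30 ± 0.14) and Fam169a (-1.32 ± 0.14). Each of these 10 lower genes was lower at 20 weeks in 12 of 12 pairs of the same genotype and time, and each passed with the same sign in Cy5 alone. The genes named here were picked for the largest differences over the same arrays, so such agreement is no separate support. In limma 11237 of 20677 genes passed, 5426 higher and 5811 lower at 20 weeks. Of these, 226 were over 2-fold higher and 28 over 2-fold lower.

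For some of the largest ratio differences, Cy3 moved and Cy5 did not pass. Cox17, a copper chaperone, had a ratio difference of 1.89 ± 0.29 and Klf2, an endothelial transcription factor, of 1.74 ± 0.29, yet in Cy5 alone they differed by -0.048 and -0.092 and in Cy3 alone by -1.60 and -1.62. Their spots were saturated in Cy5 on 7 and 2 arrays and in Cy3 on 3 and 1, so these sizes are inexact, and other probes of these genes gave -0.35 and -0.96. Of the 11237 genes, 4971 (44.2%) passed in Cy5 alone with the same sign and a larger difference than in Cy3, and 4251 (37.8%) moved more in Cy3, in the opposite direction. By construction Cy3 enters the ratio with the opposite sign. Single channels were normalized between arrays and the ratio within arrays, so channel differences need not add up to the ratio's. Evx2 (1.76 ± 0.34), Dnajb8 (1.75 ± 0.35), Syt6 (1.69 ± 0.36), Adamts4 (1.64 ± 0.37) and Eml6 (1.63 ± 0.36) were uneven: the lowest of their 12 arrays at 20 weeks lay between 0.070 and 0.20 and the highest between 4.82 and 5.23. Apob (1.74 ± 0.15), Ramp2 (1.65 ± 0.20), Eml6 and Fam169a had probes that differed, as low as 0.24 for Apob, -0.37 for Ramp2, 0.10 for Eml6 and -0.15 for Fam169a. Among 4314 pairs of probes of 1 gene that both passed, 65% had the same sign, and 1098 genes had probes called in both directions. No slide held both ages, so age and slide cannot be told apart; the count was 7032 in the floxedAlbCre arrays alone and 8672 with slide as a random block.

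**Figure D3:**
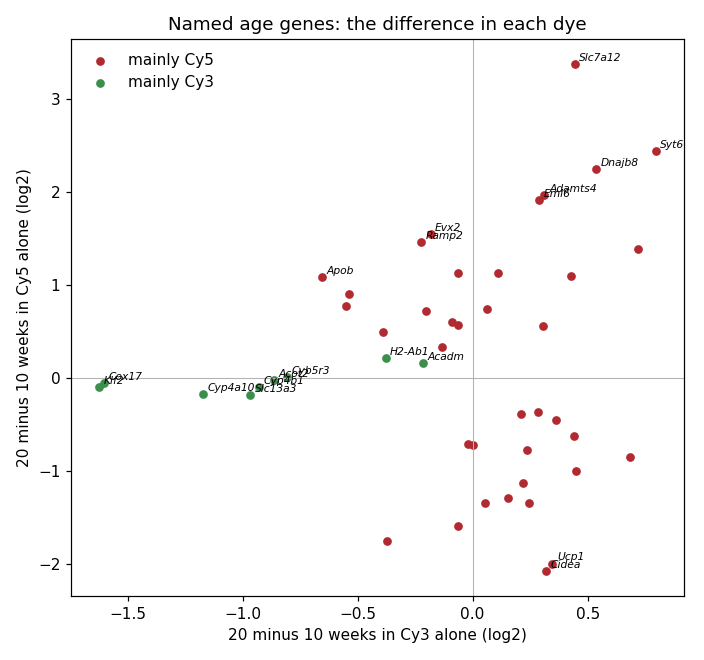
Difference between 20 and 10 weeks (log2 units) of the genes named for age, in Cy3 alone on the horizontal and Cy5 alone on the vertical axis, 1 point per gene over 24 arrays. Green points such as Cox17 (-1.60 in Cy3) moved mainly in Cy3, and red points such as Slc7a12 (3.38 in Cy5) mainly in Cy5.

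The counts of list members below stand beside 54.3% of all genes tested that passed for age. Of the adipose markers, 9 of 10 were lower at 20 weeks and 1 higher, with a median of -0.92, and all 10 passed when adjusted over the list alone. Further examples are Plin1 (-0.89 ± 0.10 in the ratio, -0.77 in Cy5 alone), which coats lipid droplets, and Car3 (-1.04 ± 0.17 in the ratio, -0.62 in Cy5 alone). As a set the list had adjusted p = 0.354 with an estimated correlation, and 0.00685 with a preset one. Of the proximal tubule markers 7 of 14 were higher and 0 lower, a share called no larger than among all genes. When adjusted over the list alone 7 passed (camera adjusted p = 0.354 with an estimated correlation, 0.00685 with a preset one). Of those 7, 4 passed as higher in Cy5 alone, and the list's median was 0.27 in the ratio, -0.031 in Cy5 alone and -0.21 in Cy3 alone. Slc22a8 (1.34 ± 0.13), Slc5a12 (0.67 ± 0.098) and Slc7a13 (0.92 ± 0.13) kept their sign in Cy5 alone, at 0.78, 1.39 and 0.50, while Slc13a3 (0.83 ± 0.098) turned to -0.18, without passing. Fatty acid oxidation had 12 of 21 higher and 2 lower, and 14 past the threshold when adjusted over the list alone, with adjusted p = 0.544 with an estimated correlation and 0.00777 with a preset one. Of those 12, 4 passed as higher in Cy5 alone, among them Cpt1a (0.57), which brings fatty acids into mitochondria, and of the 2 lower 2 passed as lower. The list's median was 0.44 in the ratio, 0.063 in Cy5 alone and -0.21 in Cy3 alone. In Cy5 alone Acadm kept its sign without passing (0.16), and Acot2 (-0.021) and Cyp4a10 (-0.17) turned, also without passing.

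The last comparisons ask whether rhythms or genotype differences depend on age. Dbp reached an amplitude of 1.70 at 10 and 1.70 at 20 weeks, and Arntl 1.22 and 1.18. For age against rhythm limma called 0 genes, with 2677 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0529. For genotype against age it called 0, with 2460 and 0.186. On simulated data without slide effects these tests recovered 59 and 40 of 100 genes that differed by 0.5 log2 units. Where few genes truly differ, recovery may be lower. Treating time as 6 levels gave 294 genes for age against rhythm, and leaving out floxedAlbCre ZT4 at 20 weeks gave 4.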

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

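The test of the dyes, the test of probe pairs and the test of movement in Cy3 were chosen only after the results were seen, and the adipose correlation was chosen before, though its 3 brown fat genes were listed later.

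Signals also appeared in single channels, which the comparisons of ratios do not use on their own. In Cy5 alone 10 of 20 clock genes were rhythmic. In Cy3 alone 9411 genes differed between the arrays of both ages.

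Clock genes cycled in the dye that the labels give to a common reference. A common reference has no time of day, so the labels' dyes would leave Cy5 flat. With 10 clock genes rhythmic in Cy5 alone and 0 in Cy3 alone, the values argue against the dyes as labelled. The hypothesis left is that the samples were in Cy5 on these arrays; it was found and tested on the same data, and the design gives no biological explanation to set against it.

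Between the ages 11237 of 20677 genes differed, and the 2 sets of arrays were hybridized on different slides. Effects on single probes would make probes of 1 gene part ways, and 65% of probe pairs had the same sign, so such effects may account for part of the pattern. In Cy3 alone 9411 genes differed between the 2 sets, so that channel moved, whatever it held. How far a shift of the reference makes the pattern stays open. Of the genes past the threshold 37.9% moved more in Cy3, between the bounds set for and against it. Age itself is an open, untested explanation, since no slide held both ages.

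Of the 10 adipose markers 9 were lower at 20 weeks and 1 higher, and as a set they had adjusted p = 0.354 with an estimated correlation. The lower values may reflect less adjoining fat in the pools. Ucp1 would then follow the 8 adipose genes outside brown fat within each age. Pearson's r was 0.13 at 10 weeks (rho -0.049; permutation p = 0.697 and 0.887) and 0.18 at 20 weeks (rho 0.22; permutation p = 0.586 and 0.487), with adjusted p = 0.697 for r and 0.887 for rho in both. Without the 2 farthest arrays r was 0.17 and 0.28. Both values of r met the bound set beforehand against such a relation. The 95% intervals were -0.48 to 0.66 and -0.44 to 0.68. Their upper limits lay below the bound set for it but above the bound against it. That a whole interval should meet a bound was not part of the prediction. The values thus argue against a relation as strong as predicted, while a weaker one cannot be excluded. A change with age itself stays open, untested.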

How the results depend on the processing

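Cy5 alone, the filter in Cy5 and slide as a block for list shifts were chosen only after the results were seen; the other alternatives were set before. The counts given first are 469 for rhythm, 48 in floxed, 84 in floxedAlbCre, 11237 for age and 0 for genotype and for the other tests of a difference. A count that moved by over 1.5 times is given here, and the cause was not tested, apart from the stricter threshold, which by construction calls fewer genes. Feature Extraction log ratio gave 4 for rhythm by age. Series matrix table gave 4 for rhythm by age. Cy3 channel alone gave 0 for rhythm, 0 for rhythm in floxed and 0 for rhythm in floxedAlbCre. Cy5 channel alone gave 41 for rhythm, 5 for rhythm in floxed and 19 for rhythm in floxedAlbCre. No filter gave 8 for rhythm by age. Above background on all 24 arrays gave 2 for rhythm by age. Array weights gave 2592 for rhythm, 92 for rhythm in floxed, 4063 for rhythm in floxedAlbCre, 1247 for genotype and 2 for rhythm by age. Time as 6 levels gave 102 for rhythm, 17 for rhythm in floxed, 24 for rhythm in floxedAlbCre and 294 for rhythm by age. 24 h and 12 h harmonics gave 222 for rhythm, 21 for rhythm in floxed and 45 for rhythm in floxedAlbCre. The fit without an age term gave 92 for rhythm, 15 for rhythm in floxed and 18 for rhythm in floxedAlbCre. Replicate block gave 7 for genotype. Slide as a fixed block gave 173 for rhythm, 31 for rhythm in floxed and 19 for rhythm in floxedAlbCre. 10 week arrays alone gave 13 for rhythm in floxed, 10 for rhythm in floxedAlbCre and 1081 for genotype. Genotype and slide partly coincided in those arrays. 20 week arrays alone gave 23 for rhythm, 2 for rhythm in floxed and 1 for rhythm in floxedAlbCre. FloxedAlbCre arrays alone gave 7032 for age. Adjusted p under 0.01 gave 163 for rhythm, 21 for rhythm in floxed and 23 for rhythm in floxedAlbCre. Without background correction, with every probe on its own, with the filter on Cy5 signal and in floxed arrays alone, no count moved by that much. Slide as a random block, run for age, gave 8672, and matching on mean intensity kept the number of lists that passed for rhythmic genes at 4. Loess with Aquantile leaves ratios as they are and tests nothing.

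For list shifts, camera gave 0 lists for age and 0 for genotype. A preset correlation gave 3 for age and 5 for genotype, fry gave 16 for age, and the exact permutation within pairs gave 1 for genotype.

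Leaving out 1 array at a time gave 307 to 742 for rhythm, 25 to 72 for rhythm in floxed, 22 to 384 for rhythm in floxedAlbCre, 0 to 0 for rhythm by genotype, 0 to 647 for genotype, 10632 to 11757 for age, 0 to 4 for rhythm by age, 0 to 0 for genotype by age. In such fits the lone array of a group is assumed to vary like the others. For rhythm in floxed the count was 26 without floxed ZT8 at 10 weeks, 25 without floxed ZT16 at 10 weeks, 30 without floxedAlbCre ZT0 at 10 weeks, 28 without floxed ZT0 at 20 weeks, 28 without floxed ZT12 at 20 weeks and 30 without floxed ZT20 at 20 weeks. For rhythm by age the count was 1 without floxed ZT12 at 10 weeks, 1 without floxedAlbCre ZT12 at 10 weeks, 2 without floxedAlbCre ZT20 at 10 weeks, 1 without floxed ZT16 at 20 weeks, 4 without floxedAlbCre ZT4 at 20 weeks and 1 without floxedAlbCre ZT20 at 20 weeks. For rhythm in floxedAlbCre the count was 33 without floxedAlbCre ZT0 at 10 weeks, 33 without floxedAlbCre ZT4 at 10 weeks, 22 without floxedAlbCre ZT12 at 10 weeks, 34 without floxedAlbCre ZT16 at 10 weeks, 47 without floxedAlbCre ZT0 at 20 weeks, 37 without floxedAlbCre ZT4 at 20 weeks, 42 without floxedAlbCre ZT8 at 20 weeks and 384 without floxedAlbCre ZT16 at 20 weeks. For rhythm the count was 307 without floxedAlbCre ZT12 at 10 weeks and 742 without floxedAlbCre ZT16 at 20 weeks. For genotype the count was 3 without floxed ZT20 at 20 weeks and 647 without floxedAlbCre ZT16 at 20 weeks. Of 43 rhythm values of named genes, the call was lost for 30 in the 20 week arrays alone, 25 in Cy5 alone, 18 without the age term, 17 with time as 6 levels, 17 in the 10 week arrays alone, 15 with slide as a fixed block, 13 at adjusted p under 0.01 and 7 with 24 h and 12 h harmonics; the settings not named here, apart from Cy3 alone, lost 0 to 3. Of 19 genotype values, 15 gained a call with array weights, 11 in the 10 week arrays alone and 4 with the replicate block. Of 47 age values, 3 lost a call and 6 turned in Cy5 alone. With 1 array left out, of 1032 rhythm values of named genes 89 lost and 1 gained a call, of 1128 age values 12 lost one, all for Arntl, and of 456 genotype values 14 gained one; none turned. The rhythm calls of Ahsg, Alas1, Msmo1 and Hspa5 ended in 17, 16, 15 and 14 of 24 such fits, and those of Cirbp and Cpt1a in 11 and 10.

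In Cy3 alone peaks moved by over 6 h with amplitudes of Npas2 0.058, Cry1 0.016, Rora 0.13, Per2 0.029, Cry2 0.12, Nr1d2 0.082, Dbp 0.023, Bhlhe40 0.11, Bhlhe41 0.095, Usp2 0.21, Nat8f5 0.093, Aqp8 0.061, Ahsg 0.16, Lonrf3 0.089, Fabp7 0.035, Nt5e 0.029, Sgk1 0.18, Rhobtb1 0.12, Avpr1a 0.13, Fkbp5 0.045, Cdkn1a 0.049, Idi1 0.088, Msmo1 0.036, Acot1 0.077, Cpt1a 0.064, Alas1 0.069 and Cirbp 0.0094. Genotype differences in Cy3 alone turned to Chrdl1 0.0098, Slc4a8 0.0064, Cyp4a14 -0.022, Ucp2 -0.18, Slc27a2 -0.077, Gsta1 0.21, Arntl -0.018 and Alb 0.24. Age differences in Cy3 alone turned to Cox17 -1.60, Evx2 -0.18, Apob -0.66, Klf2 -1.62, Ramp2 -0.22, Cidea 0.32, Ucp1 0.35, Cfd 0.68, Slc22a7 0.24, Cox8b 0.45, Fam169a 0.053, Aoc1 0.15, Mfsd2a 0.22, Cyb5r3 -0.80, Sult1d1 -0.088, Cyb5a -0.13, Plin1 0.23, Car3 0.44, Cyp4a10 -1.17, Acadm -0.22, Acot2 -0.86, Cpt1a -0.064, Slc22a8 -0.55, Slc13a3 -0.97, Slc7a13 -0.39, H2-Ab1 -0.38, Jchain -0.062, Ugt8a -0.20, Cyp4b1 -0.93, Cyp4a14 -0.54, Agt 0.0022, Igf1 0.28, Krt19 0.21 and Cldn16 0.36. By construction Cy3 enters the ratio with the opposite sign.

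In Cy5 alone age differences turned to Cox17 -0.048, Klf2 -0.092, Cyp4a10 -0.17, Acot2 -0.021, Slc13a3 -0.18 and Cyp4b1 -0.096. With time as 6 levels Hspa5 turned, with an amplitude of 0.59. The genotype difference of Alb was 0.013 with slide as a fixed block, and that of Arntl was -0.075 in the 10 week arrays alone. Signal over background limits genes such as Map1a, dim in Cy5 on many 10 week arrays. Arrays carry no replicate numbers; with the replicate block of same age and time genotype gave 7, and rhythm by genotype and genotype by age gave 0 and 0.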

Other observations

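The tests in Cy5 alone were chosen only after the result was seen; the regroupings were set before.

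Members of other lists also passed for age, with the limits of dye and slide given above, beside 54.3% of all genes tested. Immune cell markers were higher for 7 of 18 and lower for 3, and 10 passed when adjusted over the list alone, with Jchain, of antibody-making cells, at 1.19 ± 0.16 and Cd74, of antigen presentation, at 1.01 ± 0.11, both with the same sign in Cy5 alone, while H2-Ab1 (0.61 ± 0.079) did not pass in Cy5 alone (0.21). Of the 7 higher and 3 lower, 3 and 0 passed with that sign in Cy5 alone. Sex-biased kidney genes were higher for 9 of 16 and lower for 2, and 11 passed when adjusted over the list alone, among them Cyp4a14 (1.44 ± 0.21) and Ugt8a (0.95 ± 0.10), while Cyp4b1 (0.81 ± 0.10) was -0.096 in Cy5 alone, where 4 of the 9 passed as higher and 1 of the 2 as lower; the list's median was 0.34 in the ratio and -0.062 in Cy5 alone. Acetaminophen bioactivation and conjugation had 12 of 23 higher and 2 lower, and 14 past the threshold when adjusted over the list alone, with Sult1d1 (0.79 ± 0.12), Gsta2 (0.71 ± 0.14) and Cyb5a (0.51 ± 0.077) of the same sign in Cy5 alone, and Cyb5r3 (0.84 ± 0.083) at 0.011 there, where 6 of the 12 passed as higher and 1 of the 2 as lower. Camera in limma called 0 of the 34 lists for age, with adjusted p = 0.989, 0.354 and 0.354 with an estimated correlation for these 3; fry, which does not compare a list with other genes, called 16. Single genes lower at 20 weeks came from lists with members called in both directions: Agt (-0.68 ± 0.073) and Igf1 (-0.55 ± 0.064) from liver-secreted signals and their targets, with 7 of 20 higher and 3 lower, Cldn16 (-0.74 ± 0.072) from the thick ascending limb, with 2 of 8 higher and 2 lower, and Krt18 (-0.69 ± 0.072) and Krt19 (-0.52 ± 0.066) from tubular injury, with 3 of 16 higher and 7 lower.

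Rhythmic members of lists that did not pass for rhythmic genes included Idi1 (0.43 ± 0.051, ZT1.7) and Msmo1 (0.26 ± 0.059, ZT21.6) of cholesterol synthesis, Acot1 (0.36 ± 0.054, ZT23.4) and Cpt1a (0.26 ± 0.056, ZT9.9) of fatty acid oxidation, Alas1 (0.30 ± 0.067, ZT11.6), the first enzyme of heme synthesis, Cirbp, a cold-inducible RNA-binding protein (0.47 ± 0.10, ZT8.1), Hspa5, a chaperone (0.50 ± 0.11, ZT21.8), and Cldn10 (0.24 ± 0.036, ZT23.0). Leaving out 1 array ended the calls of Alas1, Msmo1, Hspa5, Cirbp and Cpt1a in 16, 15, 14, 11 and 10 of 24 fits.

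Times, genotypes or ages were regrouped 100 times per result, the real grouping included. For rhythm, 1 grouping, the real one, gave 469 genes and the highest other 27; for rhythm in floxed, 1 gave 48 and the highest other 3. For rhythm in floxedAlbCre 2 groupings gave 84 or more, and the highest other gave 178, which points to structure among these arrays. For age 1 grouping gave 11237 and the highest other 7532. For rhythm, rhythm in floxed and age, the highest other grouping stayed below the real count, so chance alone is an unlikely source of these counts. The slides stay as open as before for all of these counts. No slide held both ages, and time and slide partly coincided, most clearly in the younger arrays. With slide as a fixed block, rhythm gave 173 genes and rhythm in floxed 31. For rhythm in floxedAlbCre the share of groupings was low, but since another grouping gave more genes than the real one, the count is not read as free of chance. For rhythm by genotype, genotype, genotype by age and rhythm by age, all 100 groupings gave at least the 0 genes of the real one, with highest others of 3, 1, 127 and 5662. Every grouping meets a count of 0, so these 4 say nothing about chance. Some of these regroupings called many genes where the real one called 0. Swapping ages in some pairs only carries the difference between the 2 sets of arrays into the test of rhythm by age. The count of 5662 thus need not show any further structure of the samples.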
